A study of Mus musculus with 47 samples.

How the data were processed

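The values used were the deposited log2 expression values, 1 number per probe set and array, for 45101 probe sets of an Affymetrix mouse 3' expression array on 47 arrays. Per the submitters' processing notes, GCOS was used to make them, and no version of that software is given in the sources used here. Raised back from log2, the deposited values of an array are whole multiples of a single small step. Of all cells 55.3% were blank, and the reason for the blanks is not given in the sources used here. In all, 9988 probe sets were blank on every array and 8350 were measured on every array. Blanks were kept as blanks and were not filled. The number of measured probe sets ranged from 14758 to 23296 per array. The number of arrays per group limits the precision of each fold, and the SE printed beside it gives that precision. Total RNA had been isolated with a Qiagen kit and labelled as biotinylated cRNA, per the labels' protocols.

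Before the data were examined, a rule for scaling was set. Trimmed means were taken after removing 2% of values at each end, and quantile normalization was to be used if the highest exceeded the lowest by more than 1.2 times. The ratio was 1.46 over the probe sets measured on every array and 1.52 over all measured ones. Quantile normalization was therefore done on the 8350 common probe sets, and the remaining measured values were placed by monotone interpolation on each array. The deposited scaling was kept as an alternative.

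A probe set was kept when its value lay above the median of its array on at least 3 arrays, which left 30287. Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, and 64 were controls. Each gene was represented by the probe set with the highest mean level, giving 13509 genes, of which 5172 were measured on every array. Where 2 probe sets of a gene moved in opposite directions, this was recorded. Tests used limma with a one-way model over the 12 groups, a trend in the prior variance and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. A gene was tested only when measured on at least 3 arrays in each compared group. This last requirement was set after the blanks had been seen, since the design had not foreseen them.

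The labels do not say that the replicates come from separate animals. The p-values therefore measure spread between these samples. Age and arm of the study coincide, so age and arm are not separated where levels on Ain76A at 1 year and at 3 months are compared. That comparison is described in the last paragraph, and its counts given elsewhere carry the same limit. Crypts and villi of the same number within a group were not treated as pairs.

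Gene lists were fixed before the data were examined from general knowledge of the tissue, and 32 lists were tested when at least 3 members could be tested. The lists for Paneth cells, Wnt receptors and Wnt targets were set knowing the interest of the study, so they are not independent evidence. For each list the report gives the median log2 fold, the numbers of members that rose, fell or did not pass, and the number that pass when the adjustment runs over the list alone. Competitive tests (camera in limma) used a preset inter-gene correlation of 0.01, and were repeated with the correlation estimated from the data. Self-contained tests (fry in limma) used only genes measured on all compared arrays.

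The genes named for a comparison followed a rule. It takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, and up to 4 members of each called list. Added to these are the Paneth genes with Fzd5, Ephb2 and Ephb3 in villi of NWD1 and NWD2 mice, and Cdkn1a and Apc throughout. The rule sets which genes may be named, and not all of them are printed. Where no gene passes, the 3 smallest p-values in each direction are named. Any gene named outside this rule is said to be chosen after its values were seen. Levels are means ± SD of normalized log2 values, and folds are log2 differences ± SE from the model.

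A crypt-villus score was computed for each array from genes that differed by a log2 of at least 2 between crypts and villi in the controls of the other arm. For diet arrays it used 78 crypt-higher and 107 villus-higher genes, and for genetic arrays 189 and 212. The score is the mean of the crypt-higher minus the mean of the villus-higher genes. A spike-in level was the mean of 9 probe sets. Array measures were compared between groups by exact permutation over all regroupings of the arrays.

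Each comparison was repeated without each of its arrays in turn, with the deposited scaling, with other settings of the model, and with control arrays split at random where controls were shared. Up to 100 regroupings of the arrays gave the counts reached with mixed labels. Genes lying within 20 Mb of a knocked-out gene, or 10 Mb as an alternative, were counted with positions from the RefSeq annotation. The procedure was tested on simulated data in which 200 genes changed. At a log2 change of 1, from 40 to 73% of changed genes were recovered over the diet and genotype comparisons, and at a log2 change of 2 from 93 to 100%. False calls numbered 1 to 14. The simulated noise was drawn independently for each gene and array, without correlation between genes or differences shared by all genes of an array. These figures therefore do not give the rates on the real arrays. There, mixed labels called up to 1585 genes between wild-type and Apc1638N/+ crypts.

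Tools were R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and Python 3.11.15 with matplotlib 3.10.9.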

Results

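Messenger RNA was measured in crypts and villi of the mouse small intestine, the proliferative and the differentiated compartment of the epithelium. In a genetic arm, mice 3 months old on the purified diet Ain76A were wild type, Apc1638N/+ or p21-/-. In a diet arm, wild-type mice with a labelled age of 1 year received Ain76A, NWD1 or NWD2 for 1 year. Both NWD diets are purified diets that model a Western intake. Each of the 12 groups had 4 arrays, except the villi of NWD2 mice with 3.

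Signal and crypt-villus content differed between arrays before any gene was compared. Measured probe sets numbered 14758 to 17315 on the 4 crypt arrays of p21-/- mice and 19034 to 22020 on the 4 of wild type (exact permutation p = 0.0286, adjusted p = 0.343). Apc1638N/+ crypt arrays 1 and 2 were also low, at 15802 and 15418. The mean spike-in level was 14.45 ± 0.58 in p21-/- crypts and 12.99 ± 0.72 in wild type (exact permutation p = 0.0571). Crypt arrays 2 and 4 of wild-type mice lay between the tissues on the crypt-villus score, at -0.04 and 0.14 beside 2.09 and 1.09 for arrays 1 and 3. Crypts of NWD2 mice scored 0.98 to 2.19 and those of Ain76A mice 2.16 to 2.92 (exact permutation p = 0.0571). Villi of NWD1 mice scored -0.43, -0.47, -1.72 and -2.15, those of NWD2 mice 0.30, -1.44 and -1.37, and those of Ain76A mice -2.54 to -1.93 (exact permutation p = 0.0857 and 0.0286). Eif2s3y, a gene of the Y chromosome, was measured on all 47 arrays at 9.77 to 11.6.

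**Figure D1:**
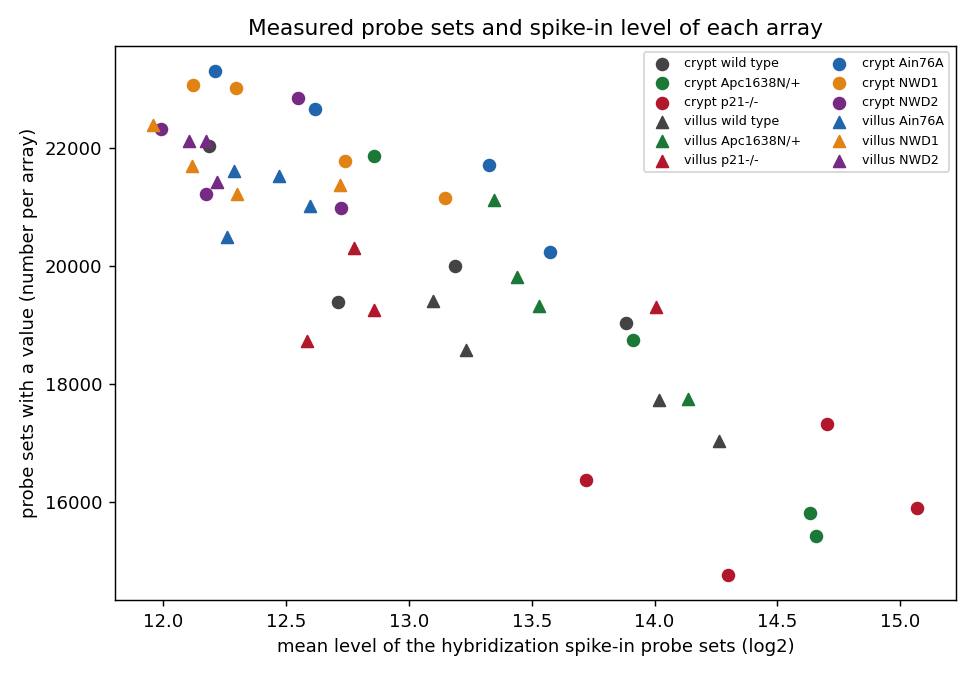
Number of measured probe sets per array (each point 1 array) by group. Arrays of p21-/- crypts held 14758 to 17315 measured probe sets.

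**Figure D2:**
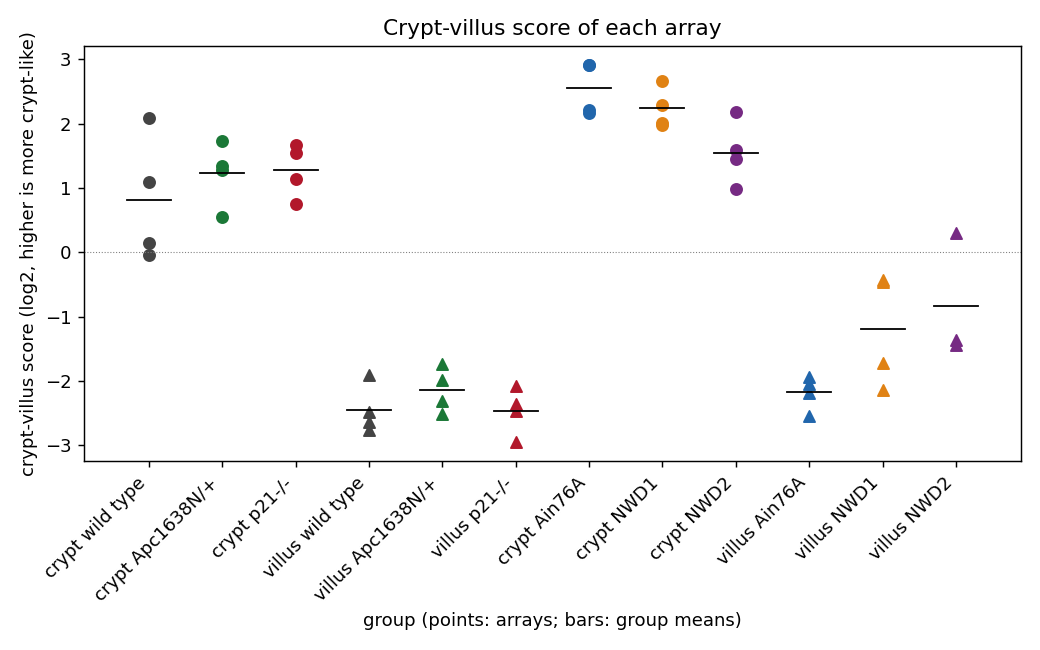
Crypt-villus score per array (each point 1 array), the mean log2 level of crypt-higher genes minus that of villus-higher genes. NWD2 crypts scored 0.98 to 2.19 and Ain76A crypts 2.16 to 2.92.

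The first question was which genes separate crypts from villi in control mice at 3 months (n = 4 per tissue). Folds here are log2 crypt over villus ± SE, so negative values are higher in villi. Secreted products of Paneth cells, which sit at the crypt base, were among the largest crypt-higher genes: Itln1 by 4.52 ± 0.55, Defa39 by 4.44 ± 0.49 and Lyz1 by 3.31. Genes of DNA replication and mitosis followed, with Cks1b higher by 3.96 ± 0.45, Cdc20 by 3.80 ± 0.46, Stmn1 by 3.71, Mcm5 by 3.16 and Mcm7 by 2.32. The ion transporters Kcnn4 (4.01 ± 0.37) and Slc12a2 (3.82 ± 0.41) and the Wnt receptor Fzd5 (2.07) were also higher in crypts. In villi, Ido1 (fold -5.98 ± 0.47), the purine enzymes Ada (-5.89 ± 0.50) and Nt5e (-5.35 ± 0.55), and Enpp3 (-5.60 ± 0.48) were higher. So were the hormone genes Sct (-4.16) and Ghrl (-3.36) and the lymphocyte genes Cd8a (-3.92) and Gzmb (-3.52).

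Of 7817 genes tested with limma, 3612 differed, 1581 higher in crypts and 2031 higher in villi, and the deposited scaling gave 1893 and 1522. The deposited scaling also moved the median fold of all genes from -0.12 to 0.04. The cell cycle list (16 genes, median 2.38) had 13 genes higher in crypts and 0 higher in villi. All 12 genes of the lymphocyte list were higher in villi (median -3.01), as were 13 of 14 enteroendocrine genes (median -2.62) and 16 of 20 interferon genes (median -1.80), with Usp18 at -3.29 and Ifih1 at -2.41. Camera called 11 of 30 lists, and 0 held with an estimated correlation, where cell cycle had adjusted p = 0.0578. Itln1, Lyz1, Cks1b, Ido1 and Cd8a stayed called whichever array was left out, while Axin2 (1.23) was lost without wild-type villus array 2 (adjusted p = 0.124) and Mptx1 (2.10) without wild-type crypt array 2 (0.0659).

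The same comparison at 1 year on Ain76A (n = 4 per tissue) asked whether the axis looks alike in the diet arm. Ang4 (4.51 ± 0.53), Defa39 (4.05 ± 0.49), Itln1 (3.78) and Lyz1 (3.67) of Paneth cells were higher in crypts, as was Olfm4 of crypt base columnar cells (4.18 ± 0.52). Cks1b (4.25 ± 0.45), Nop56 (4.10), Mad2l1 (3.83) and Slc12a2 (3.78) were higher too. Pmp22 (-5.89 ± 0.74), Clca4a (-5.86 ± 0.63), Nt5e (-5.56), the folate carrier gene Slc46a1 (-4.27) and lactase, Lct (-2.61), were higher in villi. Cdkn1a, which encodes p21, was higher in villi here (-1.66 ± 0.25, adjusted p = 4.60e-07), while in the genetic arm its fold was -0.27 ± 0.25 (adjusted p = 0.392). Another probe set of Cdkn1a, blank in p21-/- mice, had means of 9.12 ± 0.52 in wild-type crypts and 10.93 ± 0.99 in wild-type villi. On Ain76A at 1 year it had 8.86 ± 0.19 and 10.06 ± 0.27. The first probe set therefore does not show that the difference is absent in the genetic arm. Of 8822 genes, limma called 4621, 2370 higher in crypts and 2251 in villi. All 31 enterocyte genes were higher in villi (median -2.18), 27 of 29 cell cycle genes in crypts (median 2.97) and 4 of 6 Paneth genes in crypts (median 3.31). None of the 17 lists called of 31 held with an estimated correlation (cell cycle adjusted p = 0.116). With 1 array left out, the enterocyte median ran from -2.23 to -1.98 here and from -0.85 to -0.30 at 3 months. Camera called the enterocyte list at 3 months in 6 of 8 of these fits. For enterocyte genes the axis was therefore smaller at 3 months. Wild-type crypt arrays 2 and 4 of that arm lay toward villi on the crypt-villus score.

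In p21-/- mice the targeted gene was examined on every array. A probe set for Cdkn1a was blank on all 8 arrays of p21-/- mice and measured on the other 39. A second probe set for Cdkn1a was measured on all 47, with a fold of -0.77 ± 0.25 in p21-/- crypts (adjusted p = 0.0590) and 0.37 ± 0.25 in villi (adjusted p = 0.583). That probe set may lie outside the deleted part, so it checks nothing. Apc did not pass in Apc1638N/+ crypts (log2 fold 0.20 ± 0.20, adjusted p = 0.699) or villi (-0.17 ± 0.20, adjusted p = 0.948), where 1 allele carries a truncating change that need not lower the messenger.

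What does loss of 1 working Apc allele change in young mice? In crypts (n = 4 per group), Il6st, a receptor subunit for interleukin signals, rose by 1.68 ± 0.34 and Bbx by 1.33 ± 0.27, and AU040320 fell by 1.08 ± 0.22 (each adjusted p = 0.0481). Among genes that did not pass were the Paneth genes Mptx1 (1.43 ± 0.65), Mmp7 (0.77) and Pla2g2a (0.77), the enterocyte gene Alpi (-0.86) and the lymphocyte gene Gzma (-1.21). Of 8006 genes limma called 3 (2 up, 1 down) with 981 at an unadjusted p under 0.05, and with the deposited scaling 0 with 1032. No member passed in the enterocyte list (32 genes, median -0.45), which camera called at adjusted p = 0.000877, nor in the Paneth list (8 genes, median 0.56, adjusted p = 0.0391). Both were lost with an estimated correlation (adjusted p = 0.833), as were the other 2 of the 4 lists called. The crypt calls rest on few arrays: without Apc1638N/+ crypt array 3 there were 599 calls (238 up, 361 down), without Apc1638N/+ array 4 there were 24 and without wild-type crypt array 1 there were 126, and Il6st was lost without wild-type crypt array 2 or 3 or Apc1638N/+ crypt array 1, Bbx without wild-type array 2 or 3 (both up to adjusted p = 0.153) and AU040320 without wild-type array 2, 3 or 4 or Apc1638N/+ array 1 or 2 (up to 0.826). AU040320 was chosen after its values were seen, as the only call below the control.

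In villi of Apc1638N/+ mice (n = 4 per group), the heat shock gene Hspa1a rose by 2.74 ± 0.53 and Gtpbp10 by 1.62 ± 0.32 (both adjusted p = 0.0349). Related genes that did not pass were Hspa1b (2.42 ± 0.53) and the antimicrobial lectins Reg3g (2.49 ± 0.61) and Reg3b (1.43). Stat2 (-0.82) and Gbp3 (-0.97) of the interferon response did not pass either. Limma called 2 of 8087 genes, with 432 at an unadjusted p under 0.05, and the deposited scaling called 1. Of 21 immediate early and heat shock genes 1 rose, and 2 rose when adjusted over the list alone. Camera called 9 of 29 lists, among them interferon response (median -0.29, 25 genes) and lymphocytes (median -0.51, 21 genes), and 0 held with an estimated correlation (interferon adjusted p = 0.696). Hspa1a was lost without wild-type villus array 1, 2 or 3 or Apc1638N/+ villus array 1, 2 or 4 (adjusted p up to 0.257), and Gtpbp10 without Apc1638N/+ array 2 or 4 (up to 0.251), while 12 genes were called without Apc1638N/+ array 3. Without wild-type villus array 1, 0 genes were called, so Gtpbp10, measured on 3 wild-type arrays, was not called there either.

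What changes when p21, a brake on the cell cycle, is absent? In crypts of p21-/- mice (n = 4 per group), genes of the Paneth list, which includes lipase genes, rose. Pnliprp2 rose by 2.51 ± 0.55, Clps by 2.17 ± 0.45, Pla2g2a by 1.99 ± 0.31 and Mmp7 by 1.64 ± 0.37. In wild-type mice, however, Clps had a mean of 10.638 in crypts and 11.999 in villi. Pnliprp2 had 9.61 ± 1.16 in wild-type crypts and 9.28 ± 1.11 in wild-type villi. The rises of Pnliprp2 and Clps therefore do not by themselves point to Paneth cells. Of the myeloid genes Lyz2 rose by 1.71, while Csf1r (1.15) and Adgre1 (0.98) did not pass. The secretory regulator Atoh1 rose by 1.16, Efnb2 by 1.23, the p53 regulator Mdm2 by 1.32, Dnajc17 by 2.54 ± 0.37, Ntmt1 by 2.63 ± 0.67, Chd7 by 2.20, Bzw2 by 2.14 and Sp110 by 2.07. Xist rose by 2.24 ± 0.38, from 6.26 ± 0.62 on 3 wild-type arrays to 8.50 ± 0.27, on arrays that all carried Y-linked messenger. The other probe sets of Xist had values on 3 of the 47 arrays each, so this rise rests on a single probe set. The lymphocyte genes Klrd1 (-1.96 ± 0.52), Gzma (-1.89) and Ptprc (-1.57) fell, and so did the peptide transporter gene Slc15a1 (-1.80), Slc28a3 (-1.46), Ugcg (-1.37), Tnfaip3 (-1.33), Zfp943 (-1.41 ± 0.21), Rbbp6 (-1.37), Nufip2 (-1.23) and the Wnt co-receptor gene Lrp6 (-0.91).

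Limma called 392 of 7474 genes in p21-/- crypts, 258 up and 134 down, with 1544 at an unadjusted p under 0.05. The deposited scaling called 400, split 163 up and 237 down, with 274 called under both, and it moved the median fold from 0.03 to -0.13. With the spike-in level as a covariate 25 genes were called, and in a fit on only the groups compared 9. Blanks set to a low floor gave many more calls than 392, as given below. These arrays were also among the weakest by measured probe sets, and 148 genes were blank on all p21-/- crypt arrays and measured on all wild-type ones, against 1 the other way. The Paneth list (8 genes, median 1.81) had 5 members up and 0 down, or 7 up when adjusted over the list alone, and camera called it at adjusted p = 6.87e-08 but not with an estimated correlation (adjusted p = 0.207). Of 6 lymphocyte genes 3 fell (4 over the list alone, median -1.61), and of 31 enterocyte genes 2 fell (median -0.36), both lost with an estimated correlation (adjusted p = 0.772 and 0.839). Wild-type crypt arrays 2 and 4, with scores of -0.04 and 0.14, lay toward villi among the controls, and with the crypt-villus score as a covariate 374 genes were called. In all, 5 of 28 lists were called and 0 held. The count was 564 without p21-/- array 4, 259, 161 and 95 without p21-/- arrays 1, 2 and 3, and 220 and 212 without wild-type arrays 1 and 4. Pla2g2a, Dnajc17 and Zfp943 stayed called in every leave-out and with the spike-in level as a covariate, while Clps, Pnliprp2, Lyz2 and Atoh1 stayed called in every leave-out but not with the spike-in level (Pnliprp2 2.59, Lyz2 1.29, Atoh1 0.49).

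Other genes named in p21-/- crypts depended on single arrays. Mmp7 was lost without p21-/- array 3 (adjusted p = 0.0609), and Gzma and Klrd1 without wild-type array 4 (0.0566 and 0.0957). Ntmt1 and Chd7 were lost without wild-type array 1 or p21-/- array 3 (up to 0.0956 and 0.0691), and Bzw2 without these or wild-type array 2 (up to 0.108). Mdm2 was lost without wild-type array 1 or p21-/- array 2 or 3 (up to 0.108), and Slc15a1 without wild-type array 4 or p21-/- array 1 or 3 (up to 0.0758). Ptprc and Tnfaip3 were lost without wild-type array 2 or 4 or p21-/- array 2 or 3 (up to 0.205 and 0.164), and Lrp6 without wild-type array 1, 2 or 4 or p21-/- array 3 (up to 0.0679).

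In villi of p21-/- mice (n = 4 per group), Abca3, a lipid transporter gene, rose by 1.47 ± 0.22 (adjusted p = 0.000410) and Cyb561d2 by 1.24 ± 0.21 (adjusted p = 0.00282), and Unkl fell (-1.21 ± 0.24, adjusted p = 0.0306). Values that did not pass were -1.13 for Cd8a, -1.18 for Neurod1 and -1.17 for Dclk1. These were 3 of 8054 genes (2 up, 1 down) in limma, with 891 at an unadjusted p under 0.05, and 2 up with 0 down under the deposited scaling. The 8 lists called of 30 had no passing member, such as lymphocytes (19 genes, median -0.63) and enteroendocrine cells (median -0.60), and 0 held with an estimated correlation (each adjusted p = 0.667). Without p21-/- villus array 1 there were 95 calls, and without wild-type villus array 4 there were 36. Abca3 stayed called in all 8 leave-outs and Unkl was lost without wild-type array 1 or 3 or p21-/- array 2, 3 or 4 (adjusted p up to 0.227). Without p21-/- array 2 only 1 gene was called, so Cyb561d2, measured on 3 arrays per group, was not called there either.

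What does 1 year on NWD1 change in crypts? In NWD1 crypts (n = 4 per group) no gene passed of 9595, with 328 at an unadjusted p under 0.05, and the deposited scaling called 0 with 309. The smallest p-values belonged to the metallothionein gene Mt2 (2.20 ± 0.59), the brush border protease gene Mep1b (1.12 ± 0.27) and the apolipoprotein gene Apoa1 (0.97) above the control, and Dnaja4 (-1.49 ± 0.28), Nt5dc3 (-1.27) and the mitotic gene Dlgap5 (-0.89) below it. Enterocyte genes as a group lay above the Ain76A level (31 genes, median 0.69), with Slc15a1 at 1.66, Lct at 0.98 and Fabp1 at 0.63, and 10 of them passed when adjusted over the list alone. Genes of fatty acid oxidation and PPAR targets had a median of 0.42 (27 genes, 0 passing over the list alone), with Vnn1 at 1.22 and Creb3l3 at 1.07. Both lists held in camera with an estimated correlation (adjusted p = 0.0139 and 0.0139), as did proximal small intestine (11 genes, median 0.63, 2 over the list alone, adjusted p = 0.0429). Cell cycle (41 genes, median -0.39) did not hold (adjusted p = 0.356), nor did the remaining 6 of the 10 lists called of 31. The crypt-villus score of NWD1 crypts was 2.24 ± 0.32 beside 2.55 ± 0.42 in Ain76A crypts.

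In NWD1 villi (n = 4 per group), genes of Paneth cells, which normally stay in the crypt, were the main rises. Ang4 rose by 2.73 ± 0.53, from 9.37 ± 0.77 to 12.10 ± 1.21 (adjusted p = 0.0189). Defa39 rose by 2.51 ± 0.49, from 11.37 ± 1.32 to 13.87 ± 1.22 (adjusted p = 0.0189), and Lyz1 by 2.43 ± 0.40 (adjusted p = 0.00338). Itln1 (2.35 ± 0.51, adjusted p = 0.0549) and Mptx1 (1.15 ± 0.71, adjusted p = 0.998) did not pass, and Pnliprp2 (-0.02) and Clps (-0.04) lay at the control level. The Wnt receptor Fzd5 (0.40) and the crypt genes Olfm4 (1.53) and Slc12a2 (1.09) did not pass. The metallothionein gene Mt1 rose by 2.01 ± 0.41 (adjusted p = 0.0264), and the antiviral gene Oas1a fell by 1.47 ± 0.29 (adjusted p = 0.0189). Other interferon-induced genes lay below the control without passing, with Gbp2 at -1.64, Gbp3 at -1.64 and Ifit3 at -1.36.

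Limma called 5 of 9139 genes in NWD1 villi, 4 up and 1 down, with 457 at an unadjusted p under 0.05, and the deposited scaling called 11 (7 up, 4 down). The Paneth list (6 genes, median 1.75) had 2 members up and 4 not passing, or 3 up over the list alone, and camera called it with an estimated correlation too (adjusted p = 0.0165). That call was lost with the crypt-villus score as a covariate, where the median was 1.21 with 0 members called (adjusted p = 0.0616 with an estimated correlation). With the preset correlation camera still called the list there (adjusted p = 2.58e-06), and 3 members were up over the list alone. This list was set knowing the interest of the study, so it is not independent evidence. The interferon list (23 genes, median -0.79) had 1 member down and 22 not passing, or 18 down over the list alone, and it held as well (adjusted p = 0.000134). The other 7 of the 9 lists called of 31 did not hold, among them cell cycle (median 0.53, adjusted p = 0.398) and lymphocytes (median -0.72, adjusted p = 0.465). NWD1 villus arrays 1 and 2 had the most crypt-like scores, and Lyz1 levels on arrays 1 to 4 were 15.89, 15.60, 14.27 and 13.98, beside 11.95, 11.19, 13.48 and 13.41 on the Ain76A arrays. Ang4 and Defa39 were each lost without Ain76A villus array 1 or 2 or NWD1 villus array 1 or 2, with adjusted p up to 0.220, and Lyz1 without Ain76A array 2 or NWD1 array 2 (up to 0.0709). Mt1 was lost without array 2 or 3 of either group (up to 0.211), and Oas1a without Ain76A array 2, 3 or 4 or NWD1 array 1 or 2 (up to 0.256). Calls numbered 0 without Ain76A villus array 2 or NWD1 villus array 2 and 17 without NWD1 villus array 3.

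**Figure D3:**
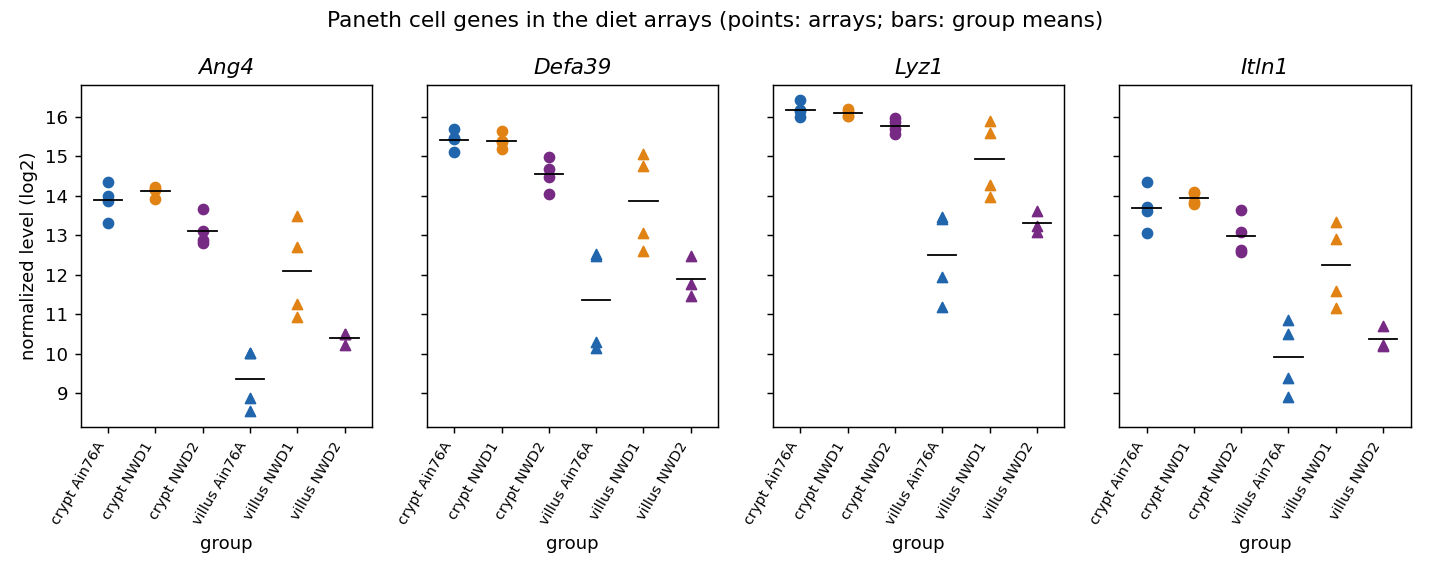
Log2 level of 4 Paneth cell genes on each diet array (each point 1 array). In NWD1 villi Lyz1 reached 15.89, 15.60, 14.27 and 13.98.

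The question for NWD2 was the same, and its crypts (n = 4 per group) gave the most calls of the diet arm. Genes of fat handling, which villus cells express, rose: the fatty acid transporter Cd36 by 3.34 ± 0.62, Acot1 by 2.52, Crat by 1.56, Creb3l3 by 1.87, Vnn1 by 2.62, Apoc2 by 2.67 and Apoa4 by 1.51. Transporters and enzymes of absorptive cells rose with them, with Slc5a4b at 3.46 ± 0.71, Slc46a1 at 2.50, Slc15a1 at 2.36, Lct at 1.93, Alpi at 1.46 and Mep1b at 1.71. Aldh1a1 (2.92), Ugt2b5 (3.10 ± 0.60), Cyp3a25 (2.53), Dnase1 (3.17 ± 0.52) and Reg3a (2.92) also rose. The heat shock genes Hsph1 (-2.37 ± 0.41), Dnaja4 (-1.69 ± 0.28) and Dnajb1 (-1.19) fell. So did the mitotic genes Mad2l1 (-1.67 ± 0.35), Bub1b (-1.48) and Cdk1 (-1.40), the crypt transcription factor genes Ascl2 (-1.49), Sox4 (-1.30) and Sox9 (-1.11), and the Paneth gene Mptx1 (-2.25 ± 0.65). Genes of lipid synthesis went both ways, with malic enzyme Me1 up (3.08 ± 0.39) and Scd2 (-2.07), Elovl5 (-1.14) and Acly (-0.83) down, 2 up and 3 down of 15 in a list that was not called (adjusted p = 0.0725). In the one-carbon list, not called either (adjusted p = 0.211), Slc46a1 rose and Shmt1 (-1.31) and Mthfd2 (-1.25) fell, 2 up and 3 down of 22. Cdkn1a had a fold of -0.33 ± 0.25 and did not pass.

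Limma called 776 of 9443 genes in NWD2 crypts, 477 up and 299 down, with 2280 at an unadjusted p under 0.05. The deposited scaling called 749 (617 up, 132 down), 574 of them shared. With the crypt-villus score as a covariate 108 were called, with 2 cell cycle genes, 0 stem cell genes and 0 Wnt targets among those that fell. Array weights and a fit on only the groups compared each called more than 776, as given below. Of 31 enterocyte genes 23 rose and 0 fell (28 up over the list alone, median 1.35), of 28 genes of fatty acid oxidation and PPAR targets 21 rose (25 over the list alone, median 1.12), and of 35 xenobiotic and antioxidant genes 19 rose (29 over the list alone, median 1.37). These 3 lists held in camera with an estimated correlation (adjusted p = 0.0305, 0.00168 and 0.0352). Of 40 cell cycle genes 13 fell (33 over the list alone, median -1.02), of 16 crypt base stem cell genes 5 fell (11 over the list alone, median -0.95) and of 14 Wnt targets 3 fell (5 over the list alone, median -0.52), all without holding (each adjusted p = 0.0818). The crypt-villus score, whose genes may include members of these lists, averaged 1.55 ± 0.50 in NWD2 crypts beside 2.55 ± 0.42 in Ain76A crypts. In total 10 of 31 lists were called and 3 held. Calls numbered 201 without NWD2 crypt array 3, 318 without NWD2 array 2, 1231 without NWD2 array 1, and 330 and 451 without Ain76A arrays 1 and 3. Cd36, Me1, Hsph1 and Mad2l1 stayed called in every leave-out and with the score as a covariate, Slc46a1 and Sox4 in every leave-out but not with the score (1.47 and -0.80), whereas without NWD2 array 3 Cdk1 (adjusted p = 0.0730), Sox9 (0.0551) and Dnajb1 (0.0851) were lost, and Ascl2 was lost without Ain76A array 1 or NWD2 array 3 or 4 (up to 0.105). Mptx1 was lost without Ain76A array 1, 3 or 4 or NWD2 array 2, 3 or 4 (up to 0.164), Acly without Ain76A array 1 or NWD2 array 2 or 3 (up to 0.108), Shmt1 without Ain76A array 1, 2 or 3 or NWD2 array 2 or 3 (up to 0.198) and Mthfd2 without these or NWD2 array 4 (up to 0.152).

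**Figure D4:**
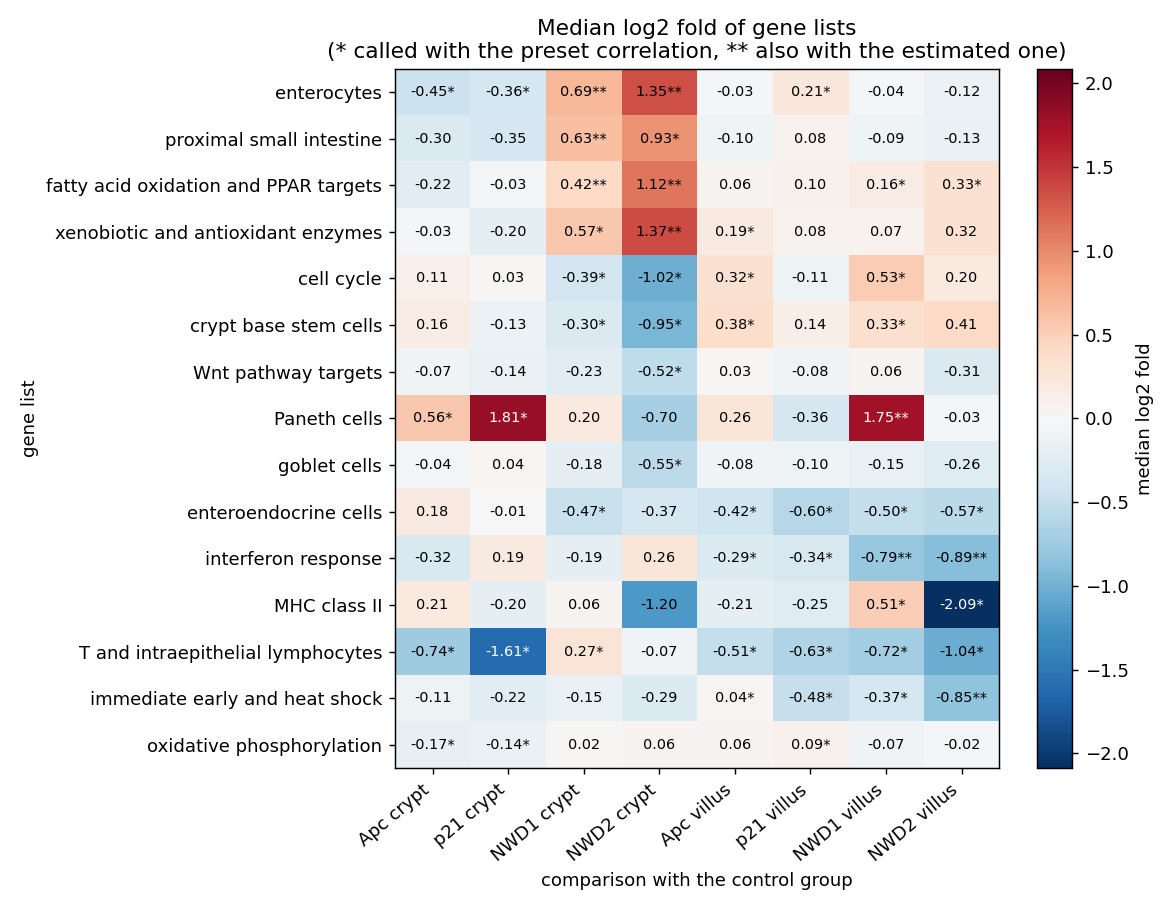
Median log2 fold of gene lists in each comparison. Enterocyte genes in NWD2 crypts had a median of 1.35.

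In NWD2 villi (n = 3, with 4 of Ain76A) the stress gene Hspa1b fell most (-3.38 ± 0.58, adjusted p = 0.00517), and the immediate early genes Dusp1 (-2.18 ± 0.43) and Bhlhe40 (-1.09) fell too. Interferon-induced genes fell, with Rsad2 at -2.42 ± 0.50, Usp18 at -2.27 and Oas1a at -1.41. Gbp3 fell with them (adjusted p = 0.00811). The antigen presentation gene H2-Aa fell (-2.64 ± 0.65), while Cd74 (-3.01 ± 0.75) and H2-Eb1 (-2.09) did not pass. Cdkn1a fell by 1.44 ± 0.27, from 13.83 ± 0.24 to 12.39 ± 0.16 (adjusted p = 0.00697), and its other probe set, at -0.88, did not pass (adjusted p = 0.400). The villus genes Nt5e (-2.46), Slc23a4 (-2.13) and Bmp8a (-2.18) fell. Ahcy of methionine metabolism rose (1.41 ± 0.26), as did Acaa2 (1.26) and Acadl (1.22 ± 0.26) of fatty acid oxidation, Atp13a3 (1.32), Rgn (1.12) and Scpep1 (0.99), and Cd36 did not pass (2.42 ± 0.67). None of the Paneth genes passed in NWD2 villi, with Ang4 at 1.04, Lyz1 at 0.80, Itln1 at 0.47 and Mptx1 at -0.52.

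Limma called 36 of 8768 genes in NWD2 villi, 8 up and 28 down, with 1005 at an unadjusted p under 0.05, and the deposited scaling called 77, of which 31 were shared. Of 20 interferon genes 4 fell (13 over the list alone, median -0.89), and of 19 immediate early and heat shock genes 2 fell (9 over the list alone, median -0.85), both held in camera with an estimated correlation (adjusted p = 0.00725 and 0.0264). The MHC class II list (5 genes, median -2.09) had 1 gene down (4 over the list alone) and did not hold (adjusted p = 0.0694). Lymphocyte genes lay at a median of -1.04 without holding (adjusted p = 0.376), and fatty acid oxidation and PPAR targets at 0.33 with 2 of 26 up (7 over the list alone, adjusted p = 0.376). The Paneth list was not called (6 genes, median -0.03, adjusted p = 0.932), and 6 of 30 lists were. NWD2 villus array 1 stood apart with the crypt-like score of 0.30. With the crypt-villus score as a covariate 13 genes were called. Cdkn1a and Hspa1b stayed called in all 7 leave-outs, while Dusp1 (adjusted p = 0.13) and Gbp3 (0.0589) were lost without NWD2 array 1, Ahcy without Ain76A array 4 (0.0522), and Rsad2 without Ain76A array 3 or 4 or NWD2 array 3 (up to 0.113). Usp18, H2-Aa, Oas1a, Slc23a4, Acadl and Rgn stayed called in 2 of 7 leave-outs each, Nt5e, Atp13a3 and Scpep1 in 1, and Acaa2, Bhlhe40 and Bmp8a in 0 (adjusted p up to 0.347, for H2-Aa), and each of the 7 arrays ended some of these calls. Counts were 22, 47, 10 and 5 without Ain76A villus arrays 1 to 4 and 16, 17 and 9 without NWD2 villus arrays 1 to 3.

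NWD2 and NWD1 were then compared directly, to ask what sets the diets apart. In crypts (n = 4 per group) Ceacam10, a glycoprotein gene, was lower with NWD2 (-3.83 ± 0.58, adjusted p = 0.00213) and stayed called in all 8 leave-outs (-4.40 to -3.62). Me1 (1.97 ± 0.39, adjusted p = 0.0592), Acot1 (1.86), Cd36 (2.25), Mptx1 (-2.22) and Cd74 (-2.14) did not pass. In villi (n = 3 and 4) Cd74 (-3.73 ± 0.75) and H2-Aa (-3.27 ± 0.65) of antigen presentation were lower with NWD2 (both adjusted p = 0.0471), each lost without any NWD1 villus array or NWD2 villus array 1 or 3 (adjusted p up to 0.710). Itln1 (-1.88), Ang4 (-1.69), Mptx1 (-1.68) and Lyz1 (-1.62 ± 0.44) did not pass. Limma called 1 of 9613 genes in crypts with 731 at an unadjusted p under 0.05, and 2 of 8893 in villi with 240, against 3 (2 up, 1 down) and 2 under the deposited scaling, and crypt calls reached 44 without NWD2 crypt array 1. With array weights many more genes were called in both tissues, as given below. Fatty acid oxidation and PPAR targets held in crypts (28 genes, median 0.64, 0 passing and 13 over the list alone, adjusted p = 0.00507 with an estimated correlation). In villi MHC class II (5 genes, median -2.55, 2 down, 4 over the list alone, adjusted p = 1.41e-05 with an estimated correlation) and Paneth cells (7 genes, median -1.62, 0 passing, 6 over the list alone, adjusted p = 0.000889) held.

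Other lists moved with those that held between NWD2 and NWD1. In crypts camera called 16 of 31 lists (7 up, 9 down) and 1 held. Those lost with an estimated correlation had medians of 0.59 for enterocytes, -0.62 for cell cycle and -0.92 for Paneth cells (each adjusted p = 0.157), -0.55 for crypt base stem cells (adjusted p = 0.153) and -1.63 for 3 B and plasma cell genes. In villi 10 of 31 were called (3 up, 7 down) and 2 held. Lost there were cell cycle (median -0.34, adjusted p = 0.434), B and plasma cells (3 genes, median -0.60, adjusted p = 0.434) and lymphocytes (median -0.35, adjusted p = 0.637). NWD1 villus arrays 1 and 2, the most crypt-like of their group, also carried the higher Paneth levels, although the mean crypt-villus score was -1.19 ± 0.88 in NWD1 and -0.84 ± 0.98 in NWD2 villi.

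Whether an effect differs between villus and crypt was tested as the villus effect minus the crypt effect (n = 4 per group, 3 for NWD2 villi). For Apc1638N/+ it was Bbx alone that passed (-2.18 ± 0.40). For p21-/- the difference was negative for genes that had risen in crypts, such as Pnliprp2 (-3.02), Clps (-2.79), Lyz2 (-2.61), Atoh1 (-1.58) and Mdm2 (-2.43), and for Adcy2 (-2.81 ± 0.46). It was positive for the brush border genes Naaladl1 (2.72), Enpep (2.01) and Slc15a1 (2.36). In wild-type mice, however, Naaladl1 and Enpep were higher in crypts (13.61 and 14.36) than in villi (12.12 and 13.20). Slc15a1 lay at 10.64 in wild-type crypts and 10.95 in wild-type villi. Wild-type crypt arrays 2 and 4 lay toward villi on the crypt-villus score (-0.04 and 0.14). The positive differences therefore rest in part on the wild-type crypt levels. For NWD2 the difference was negative for the lipid droplet gene Cidec (-3.22 ± 0.55), Slc46a1 (-3.41), Apoc2 (-2.69), Creb3l3 (-2.38) and Slc27a4 (-1.88), and positive for Nup133 (2.42), Smc2 (1.93) and Cdca7 (1.81). For NWD1 no gene passed, and Lyz1 had the smallest p among positive differences (2.52 ± 0.57, adjusted p = 0.606).

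Limma counts for these differences were 1 of 7135 for Apc1638N/+ (445 at an unadjusted p under 0.05, 0 with the deposited scaling), 116 of 6789 for p21-/- (44 up and 72 down, with the deposited scaling 216 and 71), 0 of 8581 for NWD1 (238 unadjusted, 0 deposited) and 49 of 8371 for NWD2 (10 up and 39 down, deposited 15 and 151). These counts treat crypt and villus samples as unpaired. Taking arrays of 1 number as 1 mouse raised them for p21-/- and NWD2, as given below. The deposited scaling moved the median of all genes from -0.01 to 0.16 for Apc1638N/+ and from -0.01 to 0.23 for p21-/-. Enterocyte genes had a median difference of 0.66 for p21-/- (3 of 31 up) and -1.43 for NWD2 (2 of 31 down, 25 over the list alone). Genes of the Paneth list had -2.76 for p21-/- (2 of 5 down, Pnliprp2 and Clps, and 4 over the list alone). No list held with an estimated correlation (adjusted p = 0.0977 for enterocytes with NWD2 and 0.365 for Paneth cells with p21-/-). For p21-/- counts were 61 and 6 without wild-type villus arrays 1 and 3, 365, 33, 37 and 11 without p21-/- villus arrays 1 to 4, and 37, 65, 15 and 322 without p21-/- crypt arrays 1 to 4. For NWD2 they were 4, 29, 76 and 13 without Ain76A crypt arrays 1 to 4, 489, 10, 1 and 14 without NWD2 crypt arrays 1 to 4, 15, 16, 22 and 17 without Ain76A villus arrays 1 to 4, and 1 without NWD2 villus array 1. Cidec stayed called in every leave-out, and so did Adcy2 and Lyz2. However, with the crypt-villus score as a covariate 0 genes were called for NWD2 (Cidec -1.74), and with the spike-in level 0 for p21-/- (Adcy2 -2.15, Lyz2 -2.03). Under leave-outs, for p21-/- Mdm2 stayed called in 15, Clps and Atoh1 in 12, Naaladl1 in 7, Pnliprp2 and Enpep in 6 and Slc15a1 in 5 of 16 leave-outs. For NWD2 Nup133 stayed called in 12, Creb3l3 in 11, Smc2 and Cdca7 in 5, Slc27a4 in 4 and Slc46a1 and Apoc2 in 3 of 15. Bbx was lost without wild-type crypt array 2 (adjusted p = 0.0875), and for Apc1638N/+ 18 genes passed without Apc1638N/+ crypt array 3.

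Folds were also compared between risk factors within a tissue, over genes, which are not independent replicates. Where both share controls, a correlation arises by construction. In crypts Apc1638N/+ and p21-/- folds had a correlation of 0.579, where simulated shared controls gave 0.487 and split controls 0.181, with a covariance difference of 0.0606. NWD1 and NWD2 gave 0.803 in crypts (simulated 0.502, split 0.545, covariance difference 0.0740) and 0.732 in villi (0.466, 0.468 and 0.0530). Apc1638N/+ and p21-/- gave 0.462 in villi (0.501, 0.0429 and 0.00849). Leaving out 1 array gave ranges of 0.453 to 0.718, 0.734 to 0.850, 0.643 to 0.786 and 0.318 to 0.603 in the order given. Between the arms, which share no arrays, crypt correlations were negative (-0.296 for p21-/- with NWD2 and -0.254 for Apc1638N/+ with NWD1) and villus ones positive (0.381 for p21-/- with NWD2 and 0.401 for Apc1638N/+ with NWD1). Mean crypt-villus scores of crypts also moved in opposite directions in the arms. They were 1.28 in p21-/- and 1.23 in Apc1638N/+ beside 0.82 in wild type. In the diet arm they were 2.24 with NWD1 and 1.55 with NWD2 beside 2.55 with Ain76A. The negative correlations therefore do not tell opposed effects of genotype and diet apart from crypt-villus content. Called genes seldom coincided, and for pairs with shared controls the count under independence is not what an absence of shared change would give. In crypts 1 gene rose with both Apc1638N/+ and p21-/- (0.0644 under independence), and with p21-/- and NWD2 1 rose (13.8) and 1 fell (4.84). In villi 1 gene, Oas1a, fell with both NWD1 and NWD2 (0.00322), and 0 rose with both (0.00368).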

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

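The count of genes blank in a whole group and the comparison of spike-in levels were chosen after the arrays had been examined. The difference between the ends of Gapdh transcripts was -0.41 on NWD2 crypt array 3 and -0.49 to -0.48 on the other 3, a gap, relative to the range of its group, that chance exceeds in about 1 in 20 groups. By the same measure Cdkn1a stood apart at 12.06 on Ain76A crypt array 2, and at 12.24 on NWD2 crypt array 4. Of 77 groups of array measures and targeted genes 3 passed that limit, and of 1670 groups of named genes 81 (4.85%), which is about the share that chance gives.

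Effects that differ between villus and crypt were found by a test of the difference itself, for 1 gene with Apc1638N/+, 116 with p21-/- and 49 with NWD2, at an adjusted p under 0.05 in limma. In p21-/- crypts 148 genes were blank on every array and measured on every wild-type crypt array, and 1 gene the other way. The spike-in level of p21-/- crypt arrays lay above that of wild-type crypt arrays by 1.45, in a signal that the comparisons of genes do not use.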

How the results depend on the processing

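The tests with blanks set to a low floor, with only genes measured on every array, with the spike-in level or the crypt-villus score as a covariate, without a pair of weak arrays, and at an unadjusted p under 0.01 were chosen after the results were seen. Planned ones not run were added constants of 1 and 64, since the values were already on a log2 scale, and sex as a covariate, since Y-linked messenger was on all arrays. Why a setting moved a count was not tested. Counts below are called genes.

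With the deposited scaling counts were 0 in Apc1638N/+ crypts and 1 in their villi, 11 in NWD1 villi, 77 in NWD2 villi and 3 between NWD2 and NWD1 crypts, and for the tissue difference 0 with Apc1638N/+, 287 with p21-/- and 166 with NWD2. Without a trend in the variance they were 0 in Apc1638N/+ crypts, 21 in NWD2 villi, 0 between NWD2 and NWD1 villi and 18 for the NWD2 tissue difference. With the mean over probe sets they were 0 in Apc1638N/+ crypts, 0 in their villi, 3 between NWD2 and NWD1 crypts, and for the tissue difference 0 with Apc1638N/+ and 21 with NWD2.

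Array weights gave 34 in Apc1638N/+ crypts, 6 in their villi, 151 in p21-/- crypts, 369 in p21-/- villi, 191 in NWD1 crypts, 457 in NWD1 villi, 4401 in NWD2 crypts, 1628 in NWD2 villi, 2975 and 354 between NWD2 and NWD1 crypts and villi, and 2098 between villi of different age. Tissue differences with them numbered 0 for Apc1638N/+, 408 for p21-/-, 147 for NWD1 and 2612 for NWD2. A fit on only the groups compared gave 0 in Apc1638N/+ crypts, 0 in their villi, 9 in p21-/- crypts, 8 in NWD1 crypts, 0 in NWD1 villi, 2399 in NWD2 crypts, 241 in NWD2 villi, 7 and 1 between NWD2 and NWD1 crypts and villi, 436 between crypts of different age, and for the tissue difference 0 with Apc1638N/+, 8 with p21-/- and 1220 with NWD2.

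Blanks set to a low floor gave 1 in Apc1638N/+ crypts, 0 in their villi, 3219 in p21-/- crypts, 5 in p21-/- villi, 2 in NWD1 crypts, 14 in NWD1 villi, 66 in NWD2 villi, 7 and 6 between NWD2 and NWD1 crypts and villi, and for the tissue difference 0 with Apc1638N/+, 847 with p21-/- and 20 with NWD2. With only genes measured on every array counts were 0 in Apc1638N/+ crypts, 0 in their villi, 218 in p21-/- crypts, 0 in p21-/- villi, 22 in NWD2 villi, 0 between NWD2 and NWD1 crypts, 867 between villi of different age, and for the tissue difference 0 with Apc1638N/+ and 65 with p21-/-.

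With the spike-in level as a covariate counts were 0 in Apc1638N/+ crypts, 25 in p21-/- crypts, 8 in NWD1 villi, 204 between villi of different age, and for the tissue difference 0 with Apc1638N/+, 0 with p21-/- and 162 with NWD2. With the crypt-villus score as a covariate they were 8 in Apc1638N/+ crypts, 0 in their villi, 1 in NWD1 crypts, 1 in NWD1 villi, 108 in NWD2 crypts, 13 in NWD2 villi, 0 between NWD2 and NWD1 villi, 0 for the NWD2 tissue difference and 47 between crypts of different age. Without Apc1638N/+ crypt arrays 1 and 2 there were 0 in Apc1638N/+ crypts and 0 for the Apc1638N/+ tissue difference.

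The replicate block, taking crypt and villus arrays of 1 number as 1 mouse, had a consensus correlation of 0.191. Residuals of 15 of 23 such pairs correlated above 0.1, as did 20 of 46 across groups, so the numbers were not taken to pair the samples, though 14 of 23 crypt arrays correlated best with the villus array of their own number. Pairing is not excluded, since all Ain76A pairs (0.138 to 0.287) and all NWD2 pairs (0.282 to 0.488) lay above 0.1. Other pairs went as low as -0.263. The block gave 7 in Apc1638N/+ crypts, 21 in NWD2 villi, and for the tissue difference 4 with Apc1638N/+, 382 with p21-/- and 490 with NWD2. The replicate block across groups gave 8 in Apc1638N/+ crypts, 1 in their villi, 12 in NWD2 villi, 0 between NWD2 and NWD1 villi, 221 for the NWD2 tissue difference and 276 between villi of different age. Cdkn1a in p21-/- crypts then had a log2 fold of -0.77 (adjusted p = 0.0450).

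Cdkn1a in p21-/- crypts passed with the deposited scaling (-1.02, adjusted p = 0.0199) and with blanks at a low floor (-0.77, adjusted p = 0.0274), within a range of 0.00776 to 0.336 over the alternatives. Outside the tissue differences and age, camera called 115 lists, of which 13 held with an estimated correlation, and fry called 47, of which 32 were among the 115. Genes within 20 Mb of Cdkn1a at an unadjusted p under 0.01 in p21-/- crypts gave a Fisher exact p of 0.0364. Splitting the shared controls gave correlations of 0.181 and 0.545 in crypts and 0.0429 and 0.468 in villi.

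Leaving out 1 array at a time gave 0 to 599 in Apc1638N/+ crypts, 0 to 12 in their villi, 95 to 564 in p21-/- crypts, 1 to 95 in p21-/- villi, 0 to 1 in NWD1 crypts, 0 to 17 in NWD1 villi, 201 to 1231 in NWD2 crypts, 5 to 47 in NWD2 villi, 1 to 44 and 0 to 2 between NWD2 and NWD1 crypts and villi, 219 to 1857 between crypts and 677 to 1376 between villi of different age. Tissue differences ran from 0 to 18 for Apc1638N/+, 6 to 365 for p21-/-, 0 to 0 for NWD1 and 1 to 489 for NWD2. Crypt and villus differed in 2947 to 3430 genes at 3 months and 4150 to 4320 at 1 year. Log2 folds of Cdkn1a ran from -1.12 to -0.60 in p21-/- crypts and from 0.26 to 0.51 in villi, and those of Apc from 0.04 to 0.37 in Apc1638N/+ crypts and from -0.35 to -0.04 in villi.

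Directions reversed with the crypt-villus score as a covariate for the median of cell cycle genes in NWD1 villi (-0.13), for the NWD1 tissue difference of xenobiotic (0.13), fatty acid oxidation (0.0607), bile acid (0.18), circadian (0.10) and vitamin D (0.14) lists, for the NWD2 tissue difference of xenobiotic (0.14) and cell cycle lists (-0.31), and between crypts of different age for cell cycle (-0.11), fatty acid oxidation (0.0491) and interferon (0.21) lists. They reversed for xenobiotic genes in Apc1638N/+ villi without array 4 (-0.0562), for distal genes between NWD2 and NWD1 villi without NWD2 array 1 (0.18, range -0.48 to 0.18), for Nr1d1 between crypts and villi at 3 months with a low floor (-0.11) and for Efnb2 there with the mean over probe sets (0.0040). Of 407 called genes named, 376 passed with the deposited scaling and 31 did not, 403 with the stricter filter and 4 did not, and all 407 without a filter. With array weights 381 passed, on only the groups compared 336, and with the crypt-villus score 91 passed and 85 did not.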

Other observations

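The tests of shared hybridization, of villus tissue in NWD2 crypts and of the p21-/- villus calls near the targeted gene were chosen after the results were seen. Each comparison was set against other splits of the same arrays into groups of the same sizes, 35 splits each with the real one counted, or 100 drawn for a tissue difference. Only the real split called as many genes in the wild-type crypts against villi (1 of 35, 3612 beside at most 1757), in the Ain76A crypts against villi (1 of 35, 4621 beside 44), in NWD1 villi (1 of 35, 5 beside 2), in NWD2 crypts (1 of 35, 776 beside 195) and for age in crypts (1 of 35, 984 beside 465) and villi (1 of 35, 1321 beside 19). The NWD2 tissue difference was reached by 3 of 100 splits (49, highest other 225). By this count chance is argued against for these, each with a share of splits under 0.05. No adjustment was made for the number of comparisons, so chance is not excluded. For NWD1 villi 1 of 35 is the smallest share the splits can give and 0 genes were called without Ain76A or NWD1 villus array 2, and for the NWD2 tissue difference counts without 1 array ran from 1 to 489.

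Chance cannot be excluded for the rest. As many calls came from 2 of 35 splits in p21-/- crypts (392, highest other 392), 2 of 35 in NWD2 villi (36, highest other 77), 6 of 35 in p21-/- villi (3, highest other 553), 12 of 35 in Apc1638N/+ villi (2, highest other 1168), 19 of 35 in Apc1638N/+ crypts (3, highest other 1585) and 35 of 35 in NWD1 crypts (0, highest other 1). Between NWD2 and NWD1 it was 3 of 35 in crypts (1, highest other 3) and 3 of 35 in villi (2, highest other 86). The tissue difference was matched by 47 of 100 splits for Apc1638N/+ (1, highest other 625), 7 of 100 for p21-/- (116, highest other 631) and 100 of 100 for NWD1 (0, highest other 1). For NWD1 crypts and the NWD1 tissue difference no gene was called. Every split reaches a count of 0, so these 2 results test nothing. Splits that call several times the real count, as for both tissues of Apc1638N/+, p21-/- villi, NWD2 against NWD1 villi and the tissue differences of Apc1638N/+, p21-/- and NWD2, point to a structure of the samples. What that structure is was not tested.

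Paneth cell genes were higher in NWD1 villi, with Lyz1 above every Ain76A villus array on 4 of 4 arrays. Crypt tissue carried into the villus fraction would bring all crypt transcripts in like share. The share was the linear rise over Ain76A villi, divided by the gap between Ain76A villi and NWD1 crypts. The 4 Paneth genes higher in crypts had a median share of 24.2%, beside 8.81% for 1126 other crypt-higher genes. It was 7.74% for 27 cell cycle genes and 9.81% for 10 stem cell genes. The median of the Paneth genes exceeded that of 99.34% of 10000 random sets of crypt-higher genes. This share of sets was 97.6 without NWD1 villus array 1 and 98.8 against genes matched in level. It was lowest without single genes, at 96.2 without Lyz1 and 96.5 without Itln1. Carried-over crypt tissue as the whole source therefore stays open and cannot be told apart from Paneth cells placed in villi. Of 3 crypt-higher Paneth genes outside the lysozyme and defensin families, Ang4 rose (2.73), and Itln1 (2.35) and Mptx1 (1.15) did not pass. Their median log2 fold was 2.35. Pnliprp2 and Clps, also outside these families, lay at the control level and were not among the crypt-higher genes. Hybridization shared within the families would therefore not cover Ang4, a gene already called that lies outside them. The rise of Ang4 does not test that cause for Lyz1 and Defa39, for which it stays open.

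Enterocyte genes were higher and cell cycle genes lower in NWD2 crypts. Villus tissue in these fractions would move all genes toward the NWD2 villus level in like share, but 30 enterocyte genes had moved by 49.4% (95% interval 43.4 to 55.9) and 7 interferon genes by 15.2% (6.49 to 28.7), a gap of 14.65 points between the intervals, beside 35.7% (34.0 to 37.0) for 870 other villus-higher genes, 54.5% for 1032 crypt-higher genes and 60.04% for 26 cell cycle genes. These shares are unlike, yet interferon genes also fell in NWD2 villi and the sets were not matched in level, so villus tissue cannot be told apart from a change in the crypt cells. With the crypt-villus score as a covariate, fatty acid oxidation and PPAR genes had a median of 0.92 with 9 of 28 called (camera adjusted p = 4.66e-29, up to 0.00648 over the alternatives, and 0.000313 with an estimated correlation), which argues against a shift of the kind the score measures as their whole cause. Enterocyte genes also stayed called (median 0.96, 7 of 31, adjusted p = 0.0418 with an estimated correlation), so the score may not remove all of such a shift, and the remainder stays open, while the xenobiotic list (median 0.75, 6 of 35, camera adjusted p = 2.53e-18) was lost with an estimated correlation (0.0726).

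Genes called in p21-/- mice may in large part follow the weaker crypt arrays. Over the other 39 arrays, the slope of each of 7471 genes on the spike-in level within groups correlated with its fold in p21-/- crypts at 0.536, and at 0.723 over the 392 called, beside 0.284 for Apc1638N/+, -0.362 for NWD1 and -0.347 for NWD2 crypts, though genes are not independent replicates. DNA of another strain kept around the targeted gene is argued against for most crypt calls, of which 4.34% (17 of 392) lay within 20 Mb. For the villus calls it stays open, as 66.7% (2 of 3, Abca3 and Unkl) lay there (Fisher exact p = 0.00349). With the spike-in level as a covariate 25 genes were called in p21-/- crypts and 0 for the tissue difference, and loss of p21 itself stays open as a cause.

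Between 1 year and 3 months on Ain76A, age coincides with the arm of the study, so its effects cannot be separated from other differences of the arms. In crypts (n = 4 per group) Tmigd1 (-3.59 ± 0.56), Rps4l (-2.35) and Muc3 (-2.18) were lower at 1 year, and Hnrnpu (2.47) and Chga (2.01) were higher. In villi Rgs1 (-4.44 ± 0.53), Cd7 (-3.05) and Cd8a (-3.03) were lower, and Anpep (3.58 ± 0.73), Mbl2 (3.04) and Cdkn1a (1.10) were higher. The other probe set of Cdkn1a, blank in p21-/- mice, lay the other way, at 10.06 ± 0.27 at 1 year and 10.93 ± 0.99 at 3 months. Limma called 984 of 8959 genes in crypts (554 up, 430 down, with the deposited scaling 323 and 448) and 1321 of 8073 in villi (523 up, 798 down, with the deposited scaling 875 and 984). With the crypt-villus score as a covariate 47 were called in crypts, where wild-type arrays 2 and 4 scored -0.04 and 0.14, and the medians of the cell cycle (-0.11), fatty acid oxidation (0.0491) and interferon (0.21) lists reversed. Of 16 lymphocyte genes 15 were lower in villi at 1 year (median -2.44), a list that was lost with an estimated correlation (adjusted p = 0.398), as were the other 9 called. Crypt counts were 1857, 219 and 613 without wild-type crypt arrays 1, 2 and 4 and 537 and 569 without Ain76A crypt arrays 2 and 3, and villus counts 875 and 677 without wild-type villus arrays 1 and 3.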
